A study of Mus musculus with 8 samples.

How the data were processed

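RNA from sorted splenic iNKT cells was measured on 8 single-colour oligonucleotide arrays in 4 groups of 2. Female C57BL/6 mice of 12 weeks received nothing, 1 µg αGalCer 1 h before, 4 µg αGalCer 4 weeks before, or both, all injections being intravenous. Per the labels, cells of 8 to 19 mice were pooled per array and the duplicates came from 2 independent experiments, but no label says that a replicate number marks an experiment. Per the labels' protocols, spleen cells were depleted magnetically of B cells (CD19, CD45RA), CD8 T cells (CD8a), myeloid cells (CD11b, CD11c, F4/80, Ly6C/G), red cells (TER119) and cells with CD24 or CD62L. They were then sorted on CD1d-αGalCer tetramer, TCRβ and CD44, and biotin-labelled cRNA was made from 200 ng of total RNA.

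The deposited values are intensity per probe set on a linear scale, from 2.29e-05 to 14339, with array medians of 39.1 to 48.7 that are close but not equal. The software, background correction and scaling the authors used are not given in the sources used here, and detection calls were not used here. The scale was read from the values, none of which is negative. All 8 columns of the table were used. On each array 31.4% to 33.2% of probe sets lay below 16, and 27 bacterial control probe sets, which have no target in mouse RNA, had medians of 6.43 to 9.05 and maxima of 24.9 to 51.8. Levels near those values are at background.

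Gene names came from the annotation of the array's probe sets. Of 45101 probe sets, 34958 name a single gene, 932 name several and 9211 name none; of the 34958, 34754 matched a RefSeq gene of assembly GRCm38.p6 by Entrez identifier, and 0 symbols were changed. Each of 18194 genes was represented by the probe set with the highest mean over the 8 arrays among those naming that gene alone. Probe sets naming several genes or none were tested apart and are summarised in the closing part.

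Values were transformed as log2(intensity + 16) without further normalization, so changes that start near background are compressed. A linear model with a mean per group was fitted to the 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with a trended prior; 4 residual and 5.97 prior degrees of freedom). Comparisons were Pre_unstim against Ctr_unstim, Ctr_stim against Ctr_unstim (the first response), Pre_stim against Pre_unstim (the second response), Pre_stim against Ctr_stim, and the second response minus the first. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over 18194 genes. Errors of log2 changes are standard errors of the fit.

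Gene lists were fixed before the data were examined: 23 of pathways and states and 10 of markers of other cells. Of the former, the regulatory T cell and IL-10 list was drawn partly from what this study is known for. All 33 were tested in each comparison with camera at a preset inter-gene correlation of 0.01, adjusted over the 33, with an estimated correlation and fry as alternatives. Members are counted as called over all genes and as called when adjusted over the list alone. Named genes follow a rule fixed beforehand: the 10 largest rises and 10 largest falls of each comparison between 2 groups whose arrays do not overlap, 8 each way for the difference of responses, up to 3 called members each way of each list, and a panel of 43 genes. Of the panel, 39 were measured; Rorc, Klrb1c, Ly6c1 and Ly6c2 were not analysed here because no probe set names them alone. The rule passed over 1 gene, among the falls of the second response. Tcrg-V1 and Tcrg-V4 were matched through older symbols.

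The model was tested on simulated arrays drawn for the 18194 genes, with 200 genes changed. The changes were shifts on the transformed log2 scale, so near background a 2-fold shift is a larger change in intensity. Of genes changed 2-fold, the model recovered 96% for Pre_unstim against Ctr_unstim, 99% for Ctr_stim against Ctr_unstim and 95% for Pre_stim against Pre_unstim. It recovered 97% for Pre_stim against Ctr_stim and 64% for the difference of responses. Of genes changed 4-fold it recovered 100%, 100%, 100%, 100% and 99%. False calls numbered 11, 26, 18, 22 and 13 in the same order, in each case a larger share of calls than the threshold of 0.05. On the real arrays up to 5488 genes were called, so these rates may not hold there. In Pre_unstim against Ctr_unstim, 5 of 33 simulated lists were shifted by 0.5. Camera at the preset correlation called 5 of the shifted and 0 of the others. Camera with an estimated correlation and fry gave the same counts. On the real arrays, an estimated correlation ended 66 list calls and kept 1. The simulation did not separate the methods, so it cannot show which of them holds for the real lists.

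Alternatives chosen before the data were examined were quantile normalization, median centring, a filter at the 40th percentile of mean level, the mean of a gene's probe sets, omission of probe sets marked _x_at or _s_at, a prior without trend or with robust estimation, pseudocounts of 1 and 64, a fit of only the groups compared, the replicate number as a block, omission of each array in turn, and stricter thresholds. The ratio of 3' to 5' Gapdh signal as a covariate was added after the data were seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.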

Results

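Invariant natural killer T (iNKT) cells are T cells whose receptor recognises glycolipids on CD1d, and α-galactosylceramide (αGalCer) is a glycolipid that activates them. Splenic iNKT cells sorted from female C57BL/6 mice were read on 8 arrays in 4 groups of n = 2. Ctr_unstim came from untreated mice and Ctr_stim from mice given 1 µg αGalCer 1 h earlier. Pre_unstim came from mice given 4 µg 4 weeks earlier and Pre_stim from mice given both doses. Each array held cells pooled from several mice: 8 per array in Ctr_unstim, 12 in Ctr_stim and in Pre_unstim, and 18 or 19 in Pre_stim. The tables held 45101 probe sets, of which 34958 name a single gene, and 18194 genes were tested by their brightest probe set. Levels are intensities given as mean ± standard deviation over 2 arrays, and log2 changes carry a standard error. Every gene named below with a called rise or fall between 2 groups had both arrays of 1 group above both of the other. Chance alone gives this in 1 of 3 draws of 2 against 2. Of all 18194 genes, called or not, 10407 were so separated in Pre_unstim against Ctr_unstim and 11863 in Ctr_stim against Ctr_unstim. The counts were 9539 in Pre_stim against Pre_unstim and 11727 in Pre_stim against Ctr_stim, so separation alone says little. The p-values measure spread between pooled arrays, not between mice. Between 31.4% and 33.2% of values per array lay below 16, and the 2 arrays of a group correlated at 0.993 to 0.996. The ratio of 3' to 5' signal for Gapdh, a reading of RNA integrity, was 1.45 to 1.68 in the arrays of mice without the earlier injection and 1.72 to 2.60 in those of mice injected 4 weeks earlier.

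Comparing Pre_unstim with Ctr_unstim asked what a single injection leaves behind at rest, and after 4 weeks iNKT cells carried high levels of genes known from follicular helper T cells. Il21, which encodes a cytokine that helps B cells, stood at 4.58 ± 1.19 in Ctr_unstim and 1106 ± 452 in Pre_unstim, a log2 change of 5.71 ± 0.22 (adjusted p = 5.91e-07). Cxcr5, the receptor that guides cells into B cell follicles, rose from 1.73 ± 0.309 to 875 ± 208 (log2 change 5.63 ± 0.26). Tox2, which encodes a nuclear HMG-box protein, rose from 85.1 ± 3.09 to 3868 ± 264 (5.26 ± 0.13). Il10, an anti-inflammatory cytokine gene, rose from 5.73 ± 4.29 to 77.4 ± 22.7, by 2.10 ± 0.24 (adjusted p = 2.40e-04). Among other genes with the largest rises were Gpm6b (4.22 ± 0.14), Spock2 (4.15 ± 0.20), the transcription factor Cebpa (4.04 ± 0.25), the adhesion molecule Alcam (3.88 ± 0.18) and the vitamin D receptor Vdr (3.79 ± 0.17). Among the largest falls were those of Gdpd1, from 437 ± 52.8 to 16.2 ± 13.6 (−3.88 ± 0.27), the short-chain fatty acid receptor Ffar2 (−3.74 ± 0.42), Gcnt2 (−3.72 ± 0.31) and the gelatinase Mmp9 (−3.05 ± 0.30). Of 19 follicular helper genes, 16 rose and 0 fell at a median log2 change of 1.09 (camera adjusted p = 5.91e-17, and 0.0231 with an estimated correlation). Adjusted over the list alone, 16 rose. The master regulator Bcl6 rose from 581 ± 149 to 1867 ± 263 (1.67 ± 0.16), the coactivator Pou2af1 by 3.95 ± 0.16 and the adhesion receptor Slamf6 by 1.17 ± 0.10.

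**Figure D1:**
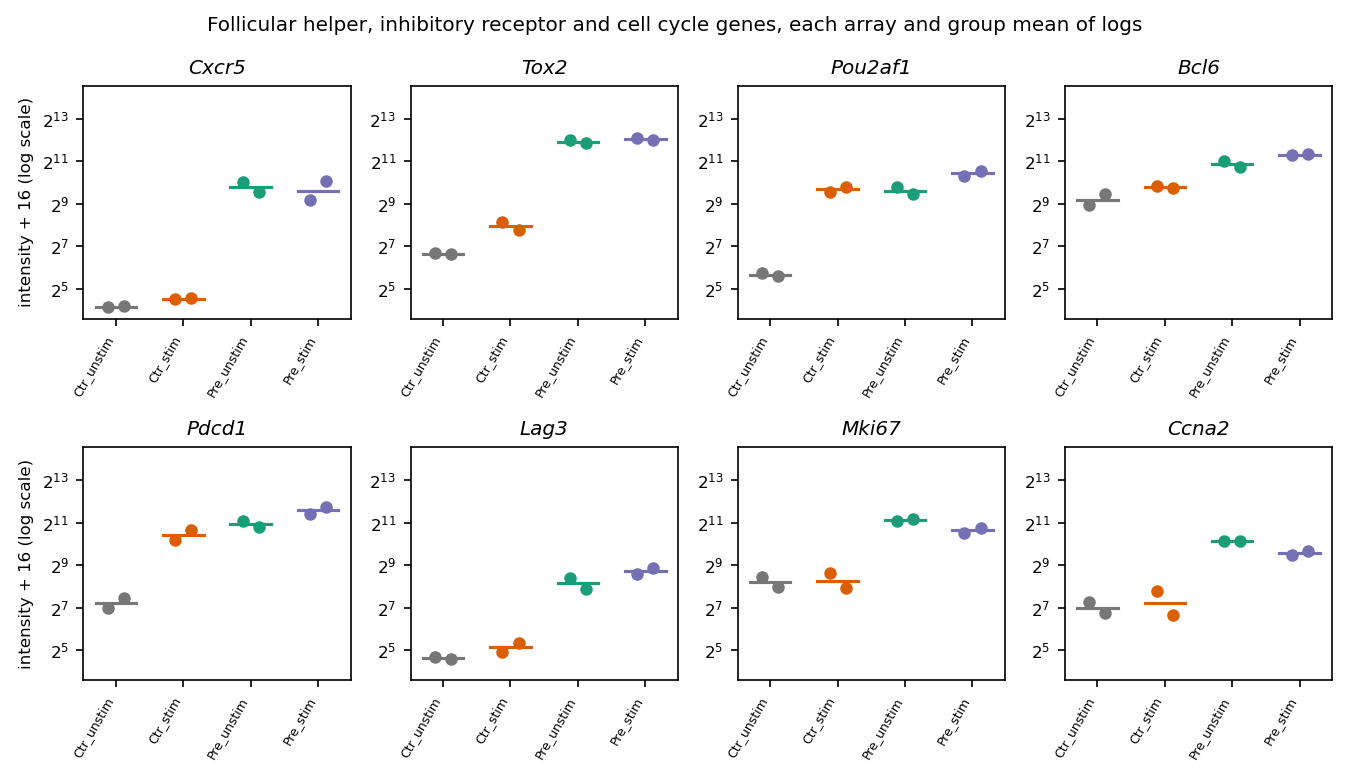
Level (log2 scale) of follicular helper, inhibitory receptor and cell cycle genes on each of the 8 arrays, by group, with the group mean. Apart from Pou2af1, the genes stand higher in both groups injected 4 weeks earlier than in the groups without that injection. The mean of Pou2af1 was 811 in Ctr_stim and 775 in Pre_unstim.

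Inhibitory receptors, which restrain T cell signalling, and the ligand Cd200 were among the genes that rose in resting cells. Pdcd1 (PD-1) went from 136 ± 36.8 to 1957 ± 288 (3.72 ± 0.20), Cd200 from 82.2 ± 13.4 to 1225 ± 8.58 (3.67 ± 0.14) and Lag3 from 9.13 ± 1.08 to 274 ± 74.1 (3.51 ± 0.21). The list of 19 inhibitory receptors and ligands split, with 8 higher and 5 lower (10 and 5 adjusted over the list alone). The lower ones included Klrc1 (−1.08 ± 0.16) and Cd160 (−0.68 ± 0.12). Its median of 0.45 was called (camera adjusted p = 0.0151), not with an estimated correlation (adjusted p = 0.205). Nor was it called after dropping genes below the 40th percentile of mean level over all probe sets (adjusted p = 0.106). Of 23 regulatory T cell and IL-10 genes, 13 rose and 3 fell (14 and 3 adjusted over the list alone), with a median of 0.49 and camera adjusted p = 8.33e-04 (adjusted p = 0.127 with an estimated correlation). That list was drawn partly from what this setting is known for, so its count is not independent evidence. Nrp1, a semaphorin receptor, rose by 2.25 ± 0.22 and Izumo1r, the folate receptor 4 of regulatory T cells, from 1123 ± 209 to 3754 ± 91.8 (1.74 ± 0.12). The interleukin-2 receptor chain Il2ra fell from 1374 ± 64 to 217 ± 56.7 (−2.60 ± 0.16). Foxp3, which defines regulatory T cells, was not called and lay at 36.1 ± 5.36 and 41.9 ± 0.672 (0.16 ± 0.16, adjusted p = 0.587). Of 24 anergy and exhaustion regulators, 15 rose and 4 fell at a median of 0.64 (camera adjusted p = 1.40e-05, and 0.0716 with an estimated correlation). They were led by Tox2 and by Egr2 (2.66 ± 0.22), an activation-induced factor linked to anergy.

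Genes of cell division stood far above their untreated level. Of 33 cell cycle genes, 31 rose and 0 fell at a median of 2.12 (camera adjusted p = 1.79e-29, and 0.205 with an estimated correlation). The proliferation marker Mki67 rose from 288 ± 67.5 to 2231 ± 84 (2.90 ± 0.22), beside the cyclins Ccna2 (3.13 ± 0.30) and Ccnb2 (3.01 ± 0.22). Of 9 NK cell markers 4 rose and 1 fell (6 and 1 adjusted over the list alone), among them Gzma (2.97 ± 0.37), Klra8 (2.58 ± 0.33) and Ncr1 (1.92 ± 0.18). Their median was 0.60 (camera adjusted p = 0.0173, 0.450 with an estimated correlation, 0.260 with the filter and 0.0699 without _x_at and _s_at probe sets). Of 7 plasma cell markers 3 rose and 0 fell (3 and 1 adjusted over the list alone), led by Jchain (2.80 ± 0.21), at a median of 0.16 (camera adjusted p = 0.0919). Of 22 type 1 genes, 14 fell and 2 rose (16 and 2 adjusted over the list alone) at a median of −0.65 (camera adjusted p = 4.11e-07, and 0.0716 with an estimated correlation). The death ligand Fasl fell by 2.28 ± 0.15, the chemokine Xcl1 from 4200 ± 112 to 1275 ± 78.2 (−1.71 ± 0.07) and Slamf7 by 1.19 ± 0.11. Fcer1g, an adaptor of NK receptors, rose by 1.71 ± 0.15. Tbx21, the regulator of type 1 cells, was not called (0.06 ± 0.14, adjusted p = 0.821). Of 31 cytokine genes 10 rose and 6 fell (12 and 7 adjusted over the list alone; camera adjusted p = 0.182 at a median of 0.31). Il2 rose from 29.3 ± 4.86 to 133 ± 11.6 (1.72 ± 0.17) and Il13 by 1.90 ± 0.36, while Csf2 fell from 520 ± 80.4 to 109 ± 35.4 (−2.12 ± 0.25). Among 21 homing and residency genes 6 rose and 2 fell (10 and 7 adjusted over the list alone) at a median of 0.28 (camera adjusted p = 0.194). The integrin Itga4 went from 762 ± 55.3 to 4903 ± 448 (2.66 ± 0.10), the gut-homing receptor Ccr9 fell by 2.70 ± 0.24 and Cxcr6 by 1.30 ± 0.19. Of 28 interferon-stimulated genes 9 fell and 0 rose (11 and 1 adjusted over the list alone) at a median of −0.38 (camera adjusted p = 3.45e-04, and 0.816 with an estimated correlation; fry adjusted p = 0.175). Oasl2 fell by 1.30 ± 0.26. In all, 1978 genes rose and 1172 fell, 709 and 241 of them by 2-fold or more. Of the calls, 62.8% were rises as deposited but 37.6% (1320 of 3512) after median centring, which moved the median change of all genes from −0.01 to −0.15. The count fell to 1883 without Ctr_unstim replicate 1, to 1893 without Ctr_unstim replicate 2, and to 2008 when the Gapdh ratio was added to the model.

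Ctr_stim against Ctr_unstim shows the first response, in which cytokine transcripts were among those that rose furthest within 1 h of αGalCer. Il13 rose from 14.1 ± 2.31 in Ctr_unstim to 9207 ± 850 in Ctr_stim, a log2 change of 8.26 ± 0.36 (adjusted p = 6.12e-07), and Il2 from 29.3 ± 4.86 to 6086 ± 454 (7.07 ± 0.17). The chemokine genes Ccl3 (44.6 ± 1.87 to 8138 ± 384, 7.07 ± 0.12), Ccl4 (7.08 ± 0.16) and Ccl1 (7.23 ± 0.32) rose as far. Il4 rose by 2.09 ± 0.20 from an already high 2162 ± 31.4 and Tnf by 4.39 ± 0.30. Il21 reached 588 ± 54.9 (4.87 ± 0.22) and Il10 141 ± 46.6 (2.84 ± 0.24). Of 31 cytokine and chemokine genes, 25 rose and 1 fell (26 and 1 adjusted over the list alone) at a median of 2.09 (camera adjusted p = 1.34e-22, and 0.0640 with an estimated correlation). They also included Il3 (5.65 ± 0.33), Csf2 (3.44 ± 0.25) and Il17a (4.08 ± 0.28).

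Transcription factors of T cell receptor signalling rose with the cytokines. Of 31 immediate-early genes, 19 rose and 0 fell at a median of 1.03 (camera adjusted p = 3.22e-13, and 0.149 with an estimated correlation). The orphan receptor Nr4a1 rose from 533 ± 394 to 6132 ± 98.2 (3.70 ± 0.38), Egr2 by 4.61 ± 0.22 and Atf3 by 5.51 ± 0.66. Of 20 NF-kB targets, 13 rose and 1 fell (14 and 1 adjusted over the list alone) at a median of 0.80 (camera adjusted p = 1.90e-08, and 0.212 with an estimated correlation). Rel, an NF-kB subunit, rose by 4.16 ± 0.21. Myc, which drives growth, rose from 324 ± 90.3 to 3703 ± 399 (3.47 ± 0.31). Of 27 ribosome biogenesis and Myc target genes 21 rose and 0 fell (23 adjusted over the list alone; median 0.82, camera adjusted p = 1.11e-15, and 0.138 with an estimated correlation), including the nucleolar gene Nolc1 (1.85 ± 0.11) and the spermidine synthase Srm (1.77 ± 0.18). Of 32 negative feedback regulators, 13 rose and 4 fell at a median of 0.36 (camera adjusted p = 5.46e-05, and 0.430 with an estimated correlation). Spry1 rose by 5.34 ± 0.25 and Spred1 by 2.31 ± 0.12. Inhibitory receptors and ligands had 9 of 19 higher and 1 lower at a median of 0.56 (camera adjusted p = 4.30e-06, and 0.0640 with an estimated correlation). Pdcd1 rose by 3.22 ± 0.20 and its ligand Pdcd1lg2 by 1.94 ± 0.12. Follicular helper genes had 10 of 19 higher and 2 lower (12 and 2 adjusted over the list alone) at a median of 0.40 (camera adjusted p = 9.36e-07, and 0.0640 with an estimated correlation). Pou2af1 rose by 4.02 ± 0.16. This list shares Il21, Il4 and Tnfsf8 with the cytokine list and Pdcd1, Cd200 and Btla with the inhibitory list. It also shares Tox2 with the anergy and exhaustion list, so the calls of these lists are not separate findings. Among the genes that fell, Txnip, an inhibitor of glucose uptake, went from 4912 ± 378 to 1015 ± 113 (−2.26 ± 0.11). The cannabinoid receptor Cnr2 fell by 2.80 ± 0.17, Plekhf1 by 2.86 ± 0.21 and the sphingosine 1-phosphate receptor S1pr4 by 1.64 ± 0.17. Counting all genes, 1619 rose and 3869 fell, 541 and 908 of them by 2-fold or more. The median log2 level over all genes was 6.32 and 6.31 in the Ctr_stim arrays and 6.48 and 6.46 in those of Ctr_unstim. The balance of rises and falls may therefore depend on scaling between arrays, as it did at rest. No omission of a single array moved the total outside 3851 to 5683.

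**Figure D2:**
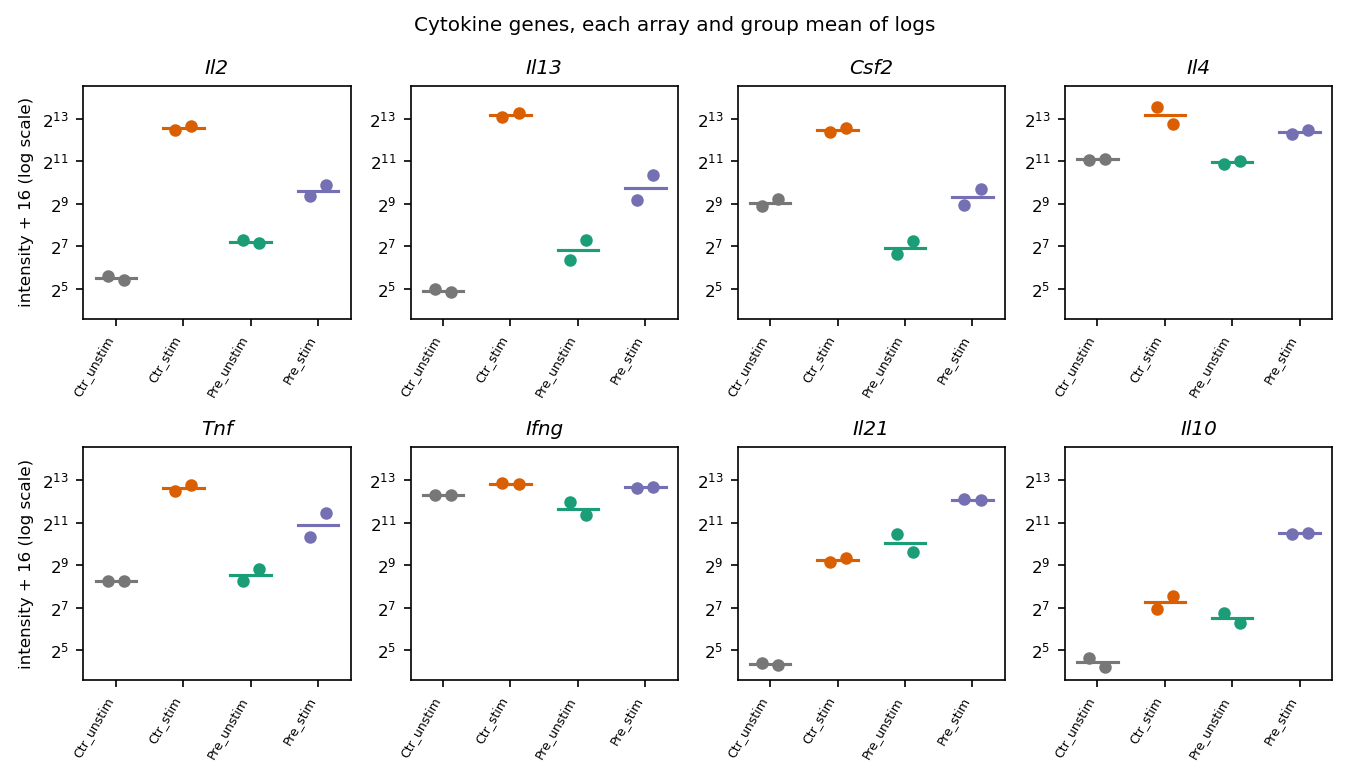
Level of cytokine genes on each of the 8 arrays (log2 scale), by group. Il10 and Il21 are highest in Pre_stim, while Il2, Il13, Tnf and Csf2 are highest in Ctr_stim.

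In cells from mice injected 4 weeks earlier, Il10, Ccl4 and Ccl3 were among the genes that a second dose raised furthest. Il10 rose from 77.4 ± 22.7 in Pre_unstim to 1435 ± 61 in Pre_stim, a log2 change of 3.98 ± 0.24 (adjusted p = 2.53e-05). Similar rises were those of Ccl4 (131 ± 29.4 to 2090 ± 266, 3.85 ± 0.16), Ccl3 (3.72 ± 0.12) and the costimulatory ligand Tnfsf9 (3.42 ± 0.30). Il21 rose from 1106 ± 452 to 4341 ± 59.6 (2.02 ± 0.22), the highest level of any group. Il13 rose by 2.95 ± 0.36 to 926 ± 517, Il2 by 2.40 ± 0.17 to 786 ± 198, Il4 by 1.44 ± 0.20 and Ifng from 3292 ± 994 to 6497 ± 137 (1.01 ± 0.15). Cytokine and chemokine genes had 22 of 31 higher and 0 lower (23 and 2 adjusted over the list alone) at a median of 1.42 (camera adjusted p = 1.65e-25, and 0.0535 with an estimated correlation). Immediate-early genes had 18 of 31 higher and 0 lower (20 and 0 adjusted over the list alone) at a median of 0.73 (camera adjusted p = 4.98e-18, and 0.123 with an estimated correlation). Nr4a1 rose by 2.99 ± 0.38, Fosl2 by 3.01 ± 0.31 and Egr3 by 2.02 ± 0.15. Negative feedback regulators had 11 of 32 higher and 2 lower (14 and 3 adjusted over the list alone) at a median of 0.41 (camera adjusted p = 8.28e-09, and 0.316 with an estimated correlation). Spry1 rose by 3.02 ± 0.25 and the G protein regulator Rgs16 from 145 ± 13 to 697 ± 27.5 (2.15 ± 0.16).

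The ligands PD-L1 (Cd274, 1.06 ± 0.07) and Cd200 (1.09 ± 0.14) and the adenosine-forming ectoenzyme CD73 (Nt5e, 0.64 ± 0.10) rose in the second response. Inhibitory receptors and ligands had 6 of 19 higher and 1 lower (8 and 4 adjusted over the list alone) at a median of 0.26 (camera adjusted p = 7.56e-04, and 0.123 with an estimated correlation). Follicular helper genes had 8 of 19 higher and 0 lower (10 and 2 adjusted over the list alone; median 0.41, camera adjusted p = 1.39e-06, and 0.0535 with an estimated correlation). Anergy and exhaustion regulators had 9 of 24 higher and 0 lower (10 and 3 adjusted over the list alone; median 0.28, camera adjusted p = 1.64e-07, and 0.0535 with an estimated correlation). NF-kB targets had 7 of 20 higher and 1 lower (7 and 2 adjusted over the list alone; median 0.33, camera adjusted p = 3.30e-06, and 0.316 with an estimated correlation). Rel rose by 3.01 ± 0.21. Ribosome biogenesis genes did not move as a set, with 1 of 27 higher and 1 lower (0 and 0 adjusted over the list alone) at a median of −0.13 (camera adjusted p = 0.817). Cell cycle genes had 5 of 33 lower and 0 higher (12 and 0 adjusted over the list alone) at a median of −0.49 (camera adjusted p = 6.35e-04, and 0.609 with an estimated correlation; fry adjusted p = 0.157). The egress receptor S1pr1 fell from 336 ± 49 to 101 ± 21.8 (−1.59 ± 0.23) and S1pr4 by 1.44 ± 0.17. Other genes that fell included Dcbld2 (−1.67 ± 0.24), the BAFF receptor Tnfrsf13c (−1.64 ± 0.18) and Txnip (−1.41 ± 0.11). A total of 577 genes rose and 1494 fell, 147 and 138 of them by 2-fold or more. Rises were 27.9% of calls as deposited, 59.9% (935 of 1560) after median centring, which moved the median change of all genes from −0.05 to 0.08, and 43.2% (600 of 1390) after quantile normalization. The total fell to 956 without Pre_unstim replicate 2, 1117 without Pre_stim replicate 1, 995 without Pre_stim replicate 2, and 1179 when only the 4 arrays compared were modelled.

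Whether the 2 responses differed was tested gene by gene, and Ccl1, Il13, Il3 and Il2 were among the genes that differed most. The difference between the responses, second minus first, was −5.45 ± 0.45 for Ccl1, −5.31 ± 0.51 for Il13 (adjusted p = 6.82e-04), −4.76 ± 0.46 for Il3 and −4.67 ± 0.25 for Il2 (adjusted p = 2.54e-05). The lipid transporter Mfsd2a (−4.17 ± 0.22), the semaphorin Sema7a (−3.89 ± 0.39) and Cd24a (−4.54 ± 0.55) also differed, rising in the first response to 1153 ± 77.7, 2018 ± 270 and 2257 ± 547. For Il10, which rose from background, the difference depended on the constant added before logs. It was 1.14 ± 0.34 with 16 (not called, adjusted p = 0.0822), −0.30 with 1 (adjusted p = 0.840) and 1.88 with 64 (adjusted p = 0.0033). Ifng was not called (0.47 ± 0.21, adjusted p = 0.238), but was without Pre_unstim replicate 1 (0.78, adjusted p = 0.0028). Genes that rose more in the second response included Nt5e, which fell by 1.05 ± 0.10 in the first (difference 1.69 ± 0.14, adjusted p = 2.97e-04), the anergy-linked ubiquitin ligase Rnf128 (1.69 ± 0.26), Pex11a (1.86 ± 0.21) and Xcl1 (0.92 ± 0.10). For Pdcd1 (−2.57 ± 0.29), Egr2 (−2.72 ± 0.31) and Pou2af1 (−3.19 ± 0.22) the difference lay below 0 and the second response began from a higher resting level.

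Gene lists were tested for the same difference. Of 7 plasma cell markers 4 had a difference below 0 and 0 above (median −1.04, camera adjusted p = 9.16e-05, and 0.150 with an estimated correlation). Ribosome biogenesis and Myc target genes had 16 of 27 with a difference below 0 and 0 above (21 and 0 adjusted over the list alone; median −0.96, camera adjusted p = 3.71e-22, and 0.150 with an estimated correlation), including Srm (−2.00 ± 0.26) and Polr1b (−1.82 ± 0.28). Cytokine and chemokine genes had 14 of 31 below and 1 above (16 and 2 adjusted over the list alone; median −0.83, camera adjusted p = 1.24e-09, and 0.150 with an estimated correlation). NF-kB targets had 5 of 20 below and 0 above (6 and 1 adjusted over the list alone; median −0.45, camera adjusted p = 9.16e-05, and 0.373 with an estimated correlation) (fry adjusted p = 0.176). Immediate-early genes had 7 of 31 below and 0 above (9 and 0 adjusted over the list alone; median −0.28, camera adjusted p = 4.13e-04, and 0.392 with an estimated correlation; fry adjusted p = 0.260). The interferon-inducible Gbp3 (−2.10 ± 0.16) and the death receptor Fas (−1.57 ± 0.20) also had differences below 0. Among 541 genes that rose by 2-fold or more in the first response, the median rise was 1.44 then and 0.44 in the second, and 304 had a called difference below 0 against 1 above. The 908 that fell by 2-fold or more had medians of −1.24 and −0.62, with 284 differences above 0. Choosing genes by their first rise inflates that rise, and a split of the arrays that removes this is given in the closing part. Over all genes 563 differences lay above 0 and 506 below (64.1% above after median centring, 751 of 1172, and 52.7% as deposited). At 2-fold or more, 108 lay above and 319 below. The count of 1069 fell to 507 and 368 without Ctr_unstim replicate 1 or 2, to 510 and 326 without Ctr_stim replicate 1 or 2, to 662 without Pre_unstim replicate 2, to 580 and 623 without Pre_stim replicate 1 or 2, and to 650 with the Gapdh ratio in the model.

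**Figure D3:**
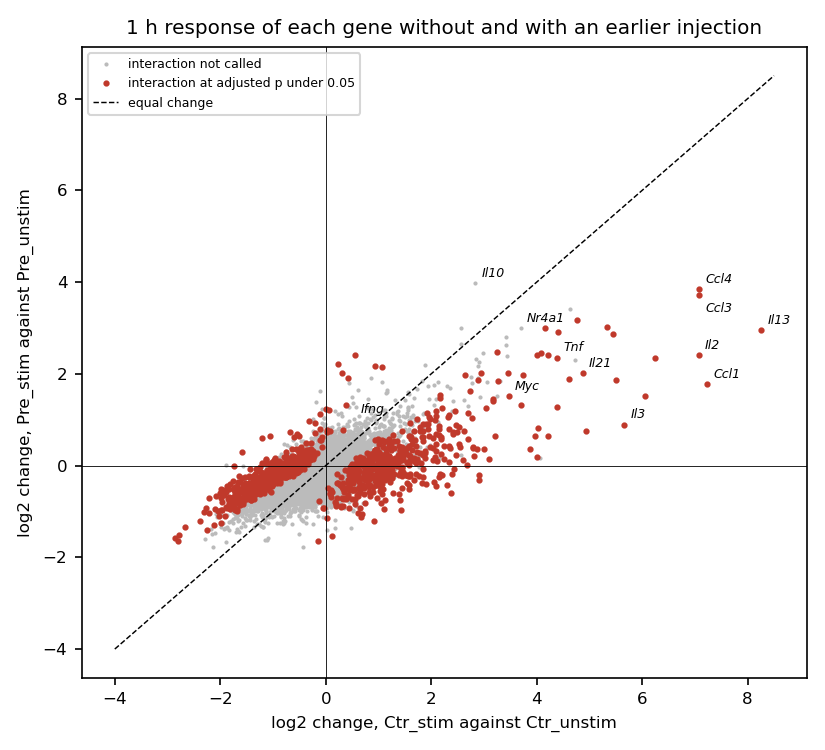
Log2 change of each gene in the first response (horizontal) and in the second (vertical), with named genes labelled. Most of the strongest first risers lie below the diagonal, and Il10 lies above it on this scale.

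After the same 1 µg dose, cells with and without the earlier injection held different cytokine transcripts. Il10 stood at 141 ± 46.6 in Ctr_stim and 1435 ± 61 in Pre_stim (3.24 ± 0.24, adjusted p = 2.08e-05). Il21 stood at 588 ± 54.9 and 4341 ± 59.6 (2.85 ± 0.22). In the other direction Il3 was lower by 4.78 ± 0.33, Ccl1 by 4.29 ± 0.32, Il13 by 3.41 ± 0.36 (9207 ± 850 against 926 ± 517), Csf2 by 3.18 ± 0.25, Il2 by 2.95 ± 0.17 and Tnf by 1.73 ± 0.30. Ifng was not called (−0.18 ± 0.15, adjusted p = 0.420), though omission of Pre_unstim replicate 1 or 2 gave adjusted p = 0.0329 and 0.0308. Egr2 was not called either (−0.07 ± 0.22, adjusted p = 0.856). Other large differences were those of Cxcr5 (5.09 ± 0.26), the BMP antagonist Sostdc1 (4.31 ± 0.30), Cebpa (4.12 ± 0.25) and Tox2 (4.11 ± 0.13) higher, and the calcitonin receptor partner Ramp3 (−4.20 ± 0.31), the kinase Fes (−4.01 ± 0.15) and Utf1 (−3.26 ± 0.16) lower.

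Pre_stim against Ctr_stim also kept several of the resting differences. Follicular helper genes had 15 of 19 higher and 1 lower (16 and 1 adjusted over the list alone; median 1.15, camera adjusted p = 2.23e-09, and 0.0756 with an estimated correlation), Bcl6 by 1.51 ± 0.16. Cell cycle genes had 31 of 33 higher and 0 lower (median 1.71, camera adjusted p = 1.87e-18, and 0.306 with an estimated correlation), Mki67 by 2.38 ± 0.22. Of 9 NK cell markers 3 were higher and 1 lower (median 0.23, camera adjusted p = 0.692). The higher ones were Gzma (1.45 ± 0.37), Klra8 (1.09 ± 0.33) and Ncr1 (0.66 ± 0.18), not called without Ctr_stim replicate 2 (adjusted p = 0.0975, 0.225 and 0.147) or Pre_stim replicate 1 (0.103, 0.183 and 0.0909). Lag3 (19.4 ± 7.24 to 409 ± 51.3, 3.60 ± 0.21), Cd200 (3.11 ± 0.14), Nrp1 (1.73 ± 0.22), Izumo1r (1.43 ± 0.12), Nt5e (2.36 ± 0.10) and Rnf128 (2.11 ± 0.18) were higher. Among 23 regulatory T cell and IL-10 genes, 12 were higher and 7 lower, but the list was not called (median 0.51, camera adjusted p = 0.310). Type 1 genes had 14 of 22 lower and 1 higher (median −0.67, camera adjusted p = 1.10e-08, and 0.0756 with an estimated correlation), Slamf7 by 1.96 ± 0.11. Type 17 genes had 9 of 15 lower and 0 higher (10 and 0 adjusted over the list alone; median −0.85, camera adjusted p = 6.76e-07, and 0.384 with an estimated correlation), Tmem176a by 2.54 ± 0.22 and Tmem176b by 2.16 ± 0.23. Ribosome biogenesis genes had 18 of 27 lower (19 adjusted over the list alone; median −0.62, camera adjusted p = 8.92e-12, and 0.302 with an estimated correlation), and cytokines and chemokines 17 of 31 with 4 higher (median −0.71, camera adjusted p = 2.64e-07, and 0.302 with an estimated correlation). Immediate-early genes had 14 of 31 lower (15 adjusted over the list alone; median −0.67, camera adjusted p = 1.17e-07, and 0.306 with an estimated correlation) and NF-kB targets 11 of 20 with 2 higher (median −0.59, camera adjusted p = 4.34e-05, and 0.384 with an estimated correlation). Examples were Nolc1 (−1.42 ± 0.11) and Crem (−1.86 ± 0.17), and outside these sets Il2ra (−3.29 ± 0.16) and Prdm1, which encodes Blimp-1 (−2.37 ± 0.24), were lower. Interferon-stimulated genes had 13 of 28 lower and 0 higher (17 and 0 adjusted over the list alone; median −0.45, camera adjusted p = 7.54e-06, and 0.542 with an estimated correlation; fry adjusted p = 0.0612), Oasl2 by 1.97 ± 0.26. In total 3419 genes were higher and 1794 lower, 723 and 428 of them by 2-fold or more. This balance may depend on scaling too, since the median log2 level over all genes was 6.46 and 6.51 in the Pre_stim arrays and 6.32 and 6.31 in those of Ctr_stim. The total of 5213 fell to 3045 without Ctr_stim replicate 2, to 3369 without Pre_stim replicate 2 and to 1617 with the Gapdh ratio in the model, where Pdcd1, Il4, Irf4 and Id3 were no longer called.

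**Figure D4:**
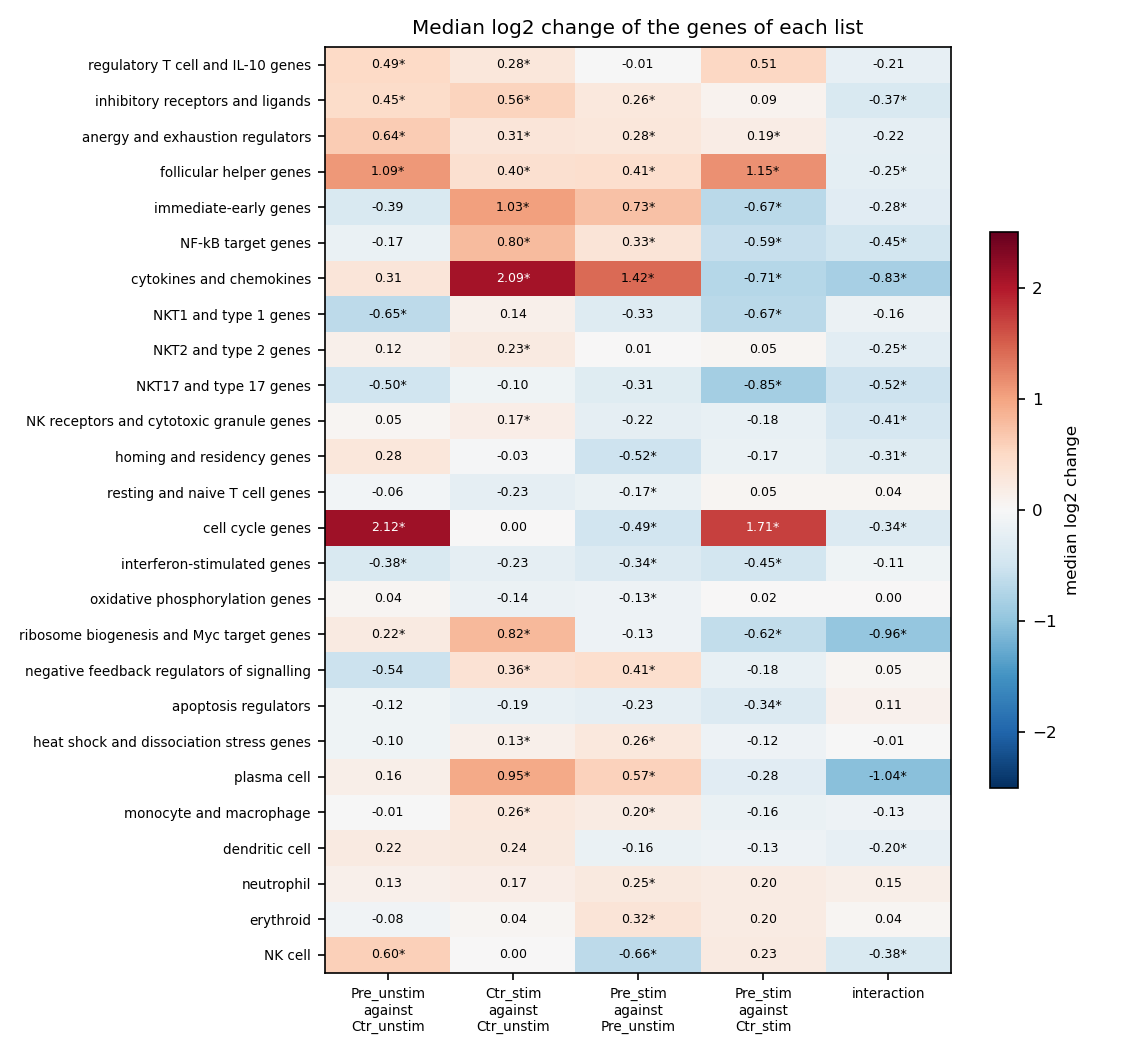
Median log2 change of each gene list (rows) in each comparison (columns), with called lists marked. Cytokine lists rise in both responses, and cell cycle and follicular helper lists are higher in both groups injected 4 weeks earlier.

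The 2 responses, which share no arrays, ran in the same direction for most genes. Across 18194 genes, which are not independent replicates, their log2 changes correlated at 0.67 (Spearman 0.57) with a slope of 0.41. Of the genes called in both, 406 rose in both where 51.3 would by chance and 1178 fell in both where 318 would, while 33 went opposite ways. Array medians were lower after the dose in both responses, so the 1178 may depend on scaling between arrays. Of the 406, 303 rose further the first time, among them Il2, Il13, Ccl3, Tnf and Nr4a1, while Il10, at this constant, rose further the second time. Genes called only in the second response numbered 454, of which 53 also had a called difference between responses. The effect of the earlier injection at rest and its effect after the dose, again from separate arrays, correlated at 0.65 (Spearman 0.52, slope 0.70). Of the genes called in both, 1364 were higher in both, such as Tox2, Cxcr5, Lag3 and Mki67, 579 were lower in both, such as Il2ra, Fasl and Csf2, and 123 went opposite ways, such as Il2 and Il13. Chance would give 372 and 116, taken over all 18194 genes with those at background included. Array medians were higher with the earlier injection both at rest and after the dose, so the 1364 may depend on scaling too.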

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

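The tests of explanations in this part were chosen after the results were seen, except the test of selection of genes on their first rise, which was written before its value was known. The alternative settings used here were chosen before the data were examined, apart from the Gapdh covariate. The limits of the other tests were set with the results at hand, and 1 limit was changed after its value was seen. For the tests of RNA integrity on the cell cycle and follicular helper lists, the limit was first a median of 1. When the follicular helper list came out at 0.99, just under it, the limit was reset to 0.5 times the uncorrected median for both lists.

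The smaller second response was seen in 541 genes raised by 2-fold or more the first time, whose median rise was 1.44 then and 0.44 later. Selection of genes on their first rise was removed by picking genes on 1 array of each control group and measuring on the other, over 4 splits of 527 to 604 genes, and a gap of 0.83 to 1.02 was left, against the limit of 0.5. Poorer RNA integrity was tested on the median difference of −1.08 (304 genes called). That median was −1.16 without Pre_stim replicate 2 and −1.13 with the Gapdh ratio in the model (249 called). Without that array, the others of mice injected earlier still had ratios of 1.72 to 2.13, against 1.45 to 1.68 in mice not injected earlier. The covariate is fitted to differences within groups, beside a mean per group. Neither fit can therefore exclude an effect of RNA integrity between groups. A smaller share of responding cells, the same for all genes, would give a single ratio of second to first rise, yet the ratios of separate arrays correlated at 0.52 to 0.65 over 8 splits (rho), with a median ratio of 0.23, 38 genes above 1 and 94 below 0 (Il10 10, Il21 5.55, Il4 0.46, Tnf 0.28, Il2 0.11 and Il13 0.09). That the earlier injection itself may have lowered the response is a candidate left open beside a changed mix of iNKT subsets, which was not tested.

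Cell cycle genes were higher in mice injected earlier, with a resting median of 2.12. Scaling between arrays left the median at 1.98 or more under quantile normalization and median centring, and the Gapdh ratio as a covariate left it at 2.10 with 30 of 33 genes called. Since the covariate is fitted within groups, it cannot exclude an effect of RNA integrity on this difference between groups. Dividing plasmablasts in the sort were tested with 7 plasma cell markers, of which 3 rose by over 1: Jchain (2.80 ± 0.21, to 642 ± 148), Irf4 (1.25 ± 0.09) and Mzb1 (1.11 ± 0.19, to 39.4 ± 2.27). Xbp1 (1092 ± 14.2 in Ctr_unstim, −0.33 ± 0.11) and Sdc1 (0.16 ± 0.22) were not called, Derl3 and Tnfrsf17 stayed near background, 2 of the 7 (Irf4 and Sdc1) sit in other lists, and Xbp1, Irf4 and Sdc1 were above 100 in untreated cells. The 3 risers may be RNA of either cell, although the sort on tetramer and TCRβ should remove plasmablasts, NK cells and conventional T cells; NK cell markers rose too (median 0.60, camera adjusted p = 0.0173, 0.450 with an estimated correlation; Gzma 2.97, Klra8 2.58 and Ncr1 1.92, with Prf1 at −0.08 not called), so dividing NK cells that passed the sort stay open, as do conventional T cells, tested only with 6 CD8 T cell markers (median −0.06, camera adjusted p = 0.861; Cd8a −0.20 and Cd8b1 −0.22, near background and not called).

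Follicular helper genes were higher in mice injected earlier, with a resting median of 1.09. B cells in the sort were tested with 17 markers, none in another list, whose median change was −0.060. Cd79a (−0.21 ± 0.15) and Ms4a1 (−0.13 ± 0.16) were not called, at 21.8 to 33.1 and 4.90 to 12.0 in the resting arrays. Cd79b alone was called higher, by 1.08 ± 0.20 to 60.6 ± 14.1 (adjusted p = 0.0043). H2-Ab1 (1.04 ± 0.36, adjusted p = 0.0760), Cd74 (0.66 ± 0.23, adjusted p = 0.0756), H2-Aa (0.62 ± 0.37) and H2-Eb1 (0.51 ± 0.31) were higher but not called. Fcer2a was called lower (−0.48 ± 0.15, adjusted p = 0.0493). The most abundant markers, Ighm at 1183 ± 16.7 and Cd74, were above 100 in untreated cells already, as were H2-Aa and Fcer2a, although depletion of CD19 cells should remove B cells. With the Gapdh ratio in the model the follicular helper median was 0.99, and 15 of 19 genes were called against 16. As for the cell cycle genes, this covariate cannot exclude an effect of RNA integrity between groups. A change in the iNKT cells after the earlier injection is a candidate left open. So are conventional T cells that passed the sort and a changed mix of iNKT subsets, which were not tested for this pattern.

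Differences between the responses, second minus first, stood out in these genes. Above 0 were Mpo (1.99), Kctd14 (1.88), Pex11a (1.86), Tmie (1.81), Snord104 (1.73), Rnf128 (1.69), Nt5e (1.69) and H2aw (1.51). Mpo belongs to the neutrophil marker list and rose from background, 7.92 ± 8.48 in Pre_unstim, to 92.9 ± 18.0 in Pre_stim. Whether neutrophils gave this rise was not tested. Below 0 were Ccl1 (−5.45), Il13 (−5.31), Il3 (−4.76), Il2 (−4.67), Cd24a (−4.54), Mfsd2a (−4.17), Sema7a (−3.89), Srxn1 (−3.82), Il21 (−2.86), Egr2 (−2.72), Pdcd1 (−2.57), Tnf (−2.04), Myc (−1.95) and Irf4 (−1.55). Calls for Tnf, Myc, Mpo, Snord104 and Tmie ended without Ctr_unstim replicate 2 or another single array: for example Tnf (adjusted p = 0.0754), Mpo (0.0647), Snord104 (0.130) and Tmie (0.0511) without Ctr_unstim replicate 2, and Myc (0.110) without Ctr_stim replicate 2. Without _x_at and _s_at probe sets the calls for H2aw (0.85, adjusted p = 0.0730) and Tmie (0.83, adjusted p = 0.109) ended. Il21 stood highest in Pre_stim, at 4341 ± 59.6, and its second rise was smaller only as a log2 change, since the first began at background (4.58 ± 1.19) and the second at 1106 ± 452, while in intensity it was 5.55 times the first. Its second probe set, at a mean of 71.0, gave a difference of 1.00 that was not called, and the mean of both gave −0.93.

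The gene lists whose difference between responses was called all had medians below 0: plasma cell −1.04, ribosome biogenesis −0.96, cytokines and chemokines −0.83, type 17 genes −0.52, NF-kB targets −0.45, NK receptors −0.41, NK cell −0.38, inhibitory receptors −0.37, cell cycle −0.34, homing and residency −0.31, immediate-early genes −0.28, type 2 genes −0.25, follicular helper genes −0.25 and dendritic cell −0.20. All 14 calls ended with an estimated correlation (adjusted p = 0.150 to 0.705). With fry, those of NF-kB targets, immediate-early genes, type 17 genes, NK receptors, NK cell, cell cycle, homing and dendritic cell ended (0.143 to 0.493). Calls also ended for type 17 genes without Pre_unstim replicate 2 (0.119) and for cell cycle without Ctr_stim replicate 1 (0.143). The homing call ended without Ctr_unstim replicate 2 (0.0969) or Pre_stim replicate 2 (0.114), and the dendritic cell call without Pre_unstim replicate 2 (0.0583) or Pre_stim replicate 1 (0.0843), with the mean of probe sets (0.0635) and with a pseudocount of 64 (0.0514). With the Gapdh ratio in the model the type 2 and homing calls ended (0.0517 each). Over single genes 563 differences lay above 0 and 506 below, but at 2-fold or more 108 lay above and 319 below.

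Probe sets that name several genes or none were not part of the report. Of 10092, the array's control probe sets left out, 1038 were called in Pre_unstim against Ctr_unstim, 832 of them higher, and 1430 in Ctr_stim against Ctr_unstim, 632 of them higher. Which transcripts they measure is not analysed here.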

How the results depend on the processing

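All alternatives in this part were chosen before the data were examined, except the Gapdh covariate, which was added after. Tests of single arrays left out assume that the lone array left in a group varies like the other groups. Signal over background is 1 limit of these arrays: 31.4% to 33.2% of values lie below 16. Unless a cause is given, the cause of a shift was not tested.

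Stricter thresholds lower counts by construction. At 2-fold or more, calls numbered 950 for Pre_unstim against Ctr_unstim, 1449 for Ctr_stim against Ctr_unstim, 285 for Pre_stim against Pre_unstim, 1151 for Pre_stim against Ctr_stim and 427 for the difference of responses. At adjusted p under 0.01 they were 1703, 3742 (within 1.5 times), 633, 3092 and 254. Pre_stim against Pre_unstim fell from 2071 to 1179 when only its 4 arrays were fitted, with fewer degrees of freedom. With the Gapdh ratio as a covariate, Pre_unstim against Ctr_unstim fell to 2008, Pre_stim against Ctr_stim to 1617 and the difference of responses to 650. The covariate costs a degree of freedom. Because the ratio differs between these groups, their differences also become less certain and can shift either way. The median difference of responses, over the 541 genes raised 2-fold or more the first time, moved from −1.08 to −1.13.

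Leaving out single arrays gave 1883 (without Ctr_unstim replicate 1) to 3287 calls for Pre_unstim against Ctr_unstim, 3851 to 5683 for Ctr_stim against Ctr_unstim, 956 (without Pre_unstim replicate 2) to 1737 for Pre_stim against Pre_unstim, 3045 (without Ctr_stim replicate 2) to 5341 for Pre_stim against Ctr_stim and 326 (without Ctr_stim replicate 2) to 865 for the difference of responses. Fewer arrays give less power by construction. Called lists ranged from 9 to 14, 13 to 14, 11 (without Pre_stim replicate 2) to 19, 10 to 13 and 12 to 16 in the same order.

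The main number of called lists was 10, 14, 18, 11 and 14. Camera with an estimated correlation called 1, 0, 0, 0 and 0, and fry called 11, 12, 14, 14 and 6, the last moved. Over all settings these called lists lost 154 calls, kept 1172 and did not change direction. Lists that were not called were not followed across settings.

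The correlation of the 2 responses, 0.67, was 0.694 with the filter, 0.529 with a pseudocount of 1 and 0.702 with 64, and 0.604 to 0.657 without single arrays. That of the effects of the earlier injection, 0.65, was 0.576 with a pseudocount of 1, 0.616 with the Gapdh covariate and 0.606 to 0.655 without single arrays.

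Named genes kept their status in 12192 comparisons of settings, lost a call in 1066 and gained 1 in 79. Their direction turned in 3. Ighm in Ctr_stim against Ctr_unstim was −0.79 and became 0.97 with the mean of its probe sets (adjusted p = 0.0088), and in Pre_stim against Ctr_stim 0.79 became −0.12. Tox2 in the difference of responses was −1.15 and became 0.22 without _x_at and _s_at probe sets, where its other probe set lies at a mean of 15.6. The log2 difference of 3' and 5' Gapdh signal in Ctr_unstim moved from 0.75 to 0.73 with a pseudocount of 64, by construction.

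The replicate block, fitted with the replicate number, gave 3600, 5912, 2590, 5698 and 1539 calls. The deviations of same-numbered arrays correlated at 0.04 to 0.20 between groups, all above 0, and the block raised the calls in each comparison. Both go with pairing by number. The correlations are weak, however, and no label states a pairing, so the paired fit is not used. Under it the apoptosis list in Pre_stim against Ctr_stim had adjusted p = 0.0562 (median −0.34). Among named genes 2 calls ended (Cd79a and Bank1, Pre_stim against Ctr_stim) and 11 were gained; no other call of a named gene or of a list called in the main fit changed.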

Other observations

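The lists and comparisons of this part were fixed before the data were examined. Of the tests here, only the Gapdh covariate was added after the data were seen. Single NK receptor and granule genes of resting cells moved both ways after the earlier injection. The Ly49 receptors Klra7 (67.5 ± 3.11 to 501 ± 194, 2.58 ± 0.28) and Klra8 (2.58 ± 0.33) and the granzymes Gzma (586 ± 304 to 4412 ± 532, 2.97 ± 0.37) and Gzmk (1.43 ± 0.16) rose, while Klrc1 fell by 1.08 ± 0.16 and Slamf7 by 1.19 ± 0.11. Of 25 NK receptor and granule genes 7 rose and 8 fell (10 and 9 adjusted over the list alone) at a median of 0.05 (camera adjusted p = 0.917). In the first response 5 rose and 0 fell, such as Cst7 (0.71 ± 0.13), at a median of 0.17 (camera adjusted p = 0.0326, and 0.580 with an estimated correlation). That call ended without Ctr_unstim replicate 1 (median 0.10), Ctr_stim replicate 2 (0.10), Pre_stim replicate 1 (0.17) and Pre_stim replicate 2 (0.17). It also ended with the mean of probe sets (camera adjusted p = 0.0581), with only the groups compared (0.0661) and with the Gapdh covariate (median 0.08, 0.240). With fry the adjusted p was 0.180. Of 9 NK cell markers 4 rose and 1 fell at rest (6 and 1 adjusted over the list alone; median 0.60, camera adjusted p = 0.0173, and 0.450 with an estimated correlation), and the call ended with the filter (0.260) and without _x_at and _s_at probe sets (0.0699). Ncr1, a receptor of NK cells, rose from 5.47 ± 0.665 to 66.1 ± 16.2 (1.92 ± 0.18) and Eomes by 0.97 ± 0.19. NK cells in the sort may add to these, yet 5 of the 9 markers sit in other lists, Prf1, Gzma and Klre1 were above 100 in untreated cells, and the sort on tetramer and TCRβ should remove NK cells. In the second response the 9 had a median of −0.66 with 2 lower (5 adjusted over the list alone; camera adjusted p = 0.0087, and 0.316 with an estimated correlation), a call that ended without Pre_stim replicate 2 (−0.39, adjusted p = 0.108) and with the filter (0.0902).

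Among lineage factors at rest, Id3 rose from 45.8 ± 21.2 to 691 ± 190 (3.53 ± 0.24) and Myb from 578 ± 47.4 to 3569 ± 5.01 (2.60 ± 0.12), while Runx3 fell by 1.38 ± 0.14. The list of 20 had 7 higher and 3 lower (7 and 6 adjusted over the list alone) and was not called (median −0.02, mean 0.43, camera adjusted p = 0.383), so its median and mean differ in sign. Among type 2 genes the interleukin-4 receptor Il4ra fell by 1.59 ± 0.17 at rest, and the list had 6 of 16 higher and 4 lower (median 0.12, camera adjusted p = 0.575). In the first response 7 rose and 2 fell (7 and 3 adjusted over the list alone), with Ccr4 up by 1.45 ± 0.17 (median 0.23, camera adjusted p = 0.0116, and 0.173 with an estimated correlation). Of 15 type 17 genes 7 fell and 1 rose at rest (8 and 2 adjusted over the list alone), including Tmem176b (−2.11 ± 0.23) and Itgb3 (−1.45 ± 0.23), at a median of −0.50 (camera adjusted p = 0.0165, and 0.816 with an estimated correlation). The call ended without Ctr_unstim replicate 1 (0.0629) and Pre_unstim replicate 1 (0.111), with median centring (0.102) and with fry (0.189). Resting and naive T cell genes had 4 of 18 higher and 7 lower at rest (median −0.06, mean 0.10, camera direction down, adjusted p = 0.551), where the signs differ, with Il6ra up by 1.76 ± 0.19 and Il7r down by 0.50 ± 0.08.

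At rest Bcl2, which blocks apoptosis, fell from 1654 ± 146 to 640 ± 28.9 (−1.35 ± 0.12) and Bik by 1.53 ± 0.17, while Bid rose by 0.67 ± 0.14; 4 of 20 apoptosis genes rose and 5 fell (median −0.12, camera adjusted p = 0.102). After the dose 9 of 20 were lower and 4 higher in Pre_stim (median −0.34, camera adjusted p = 0.0414, and 0.302 with an estimated correlation), Bcl2l1 by 1.13 ± 0.15, but the call ended without Ctr_stim replicate 1 (0.0667) or Pre_stim replicate 2 (0.0594), with median centring (0.0654), without _x_at and _s_at probe sets (0.0672), with a pseudocount of 64 (0.0520) and with the Gapdh covariate (0.0614). Of 17 glycolysis genes 7 rose and 1 fell at rest (8 and 1 adjusted over the list alone; median 0.20, camera adjusted p = 0.216), Pfkp by 0.88 ± 0.10 and the glucose transporter Slc2a3 down by 1.04 ± 0.09. The first response raised Hk2 (1.85 ± 0.30) and Ldha (0.88 ± 0.11) and lowered the respiratory genes Sdhd (−0.73 ± 0.10) and Ndufs7 (−0.57 ± 0.09), with 1 of 29 oxidative phosphorylation genes higher and 6 lower (median −0.14, camera adjusted p = 0.148). In the second response that list was called at a median of −0.13 with 1 higher and 2 lower (camera adjusted p = 0.0222, and 0.651 with an estimated correlation), and the call ended without Pre_unstim replicate 2 (0.308) or Pre_stim replicate 2 (0.323), with median centring (0.386), the filter (0.207) and fry (0.130). Camera did not call TCR signalling components in any comparison, though fry called them higher in the second response (fry adjusted p = 0.0359 against camera 0.0798), and at rest 3 of 23 rose and 3 fell (median −0.03, camera adjusted p = 0.917), among them Prkcq (0.49 ± 0.07) and Rasgrp1 (−0.45 ± 0.07). Ribosome biogenesis genes had 7 of 27 higher and 0 lower at rest (11 and 0 adjusted over the list alone; median 0.22, camera adjusted p = 0.0025, and 0.729 with an estimated correlation), a call that ended without Pre_unstim replicate 2 (0.0626) and with fry (0.0924). Heat shock genes had 4 of 13 higher and 0 lower in the first response (median 0.13, camera adjusted p = 0.0223, and 0.534 with an estimated correlation). The call ended without Ctr_unstim replicate 1 (median 0.02) or Ctr_stim replicate 2 (median 0.07) and with fry (adjusted p = 0.381).

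In the first response the class II genes H2-Ab1 (82.8 ± 19.1 to 339 ± 141, 1.80 ± 0.36) and H2-Eb1 (1.63 ± 0.31) and the factor Irf8 (186 ± 29.8 to 1108 ± 206, 2.47 ± 0.23) rose, and the B cell list had 4 of 17 higher and 2 lower (median 0.01, camera adjusted p = 0.202). Cd74 was among the higher ones (1.23 ± 0.23). Ighm, among the lower ones at −0.79 ± 0.12, became 0.97 with the mean of its probe sets. Immunoglobulin genes outside the list were among the 541 genes raised by 2-fold or more. Examples were Igk, Igkv8-30 and Igha, which rose by 1406, 1055 and 368 in intensity. Jchain rose from 78 ± 17.9 to 595 ± 131 (2.70 ± 0.21) and Tnfrsf17 by 1.94 ± 0.12 from background, in a plasma cell list with 5 of 7 higher and 1 lower (median 0.95, camera adjusted p = 9.07e-05, and 0.0790 with an estimated correlation). Monocyte and macrophage markers had 4 of 17 higher and 0 lower (median 0.26, camera adjusted p = 0.0056, and 0.504 with an estimated correlation; fry adjusted p = 0.118), and dendritic cell markers 3 of 12 higher and 1 lower (median 0.24, camera adjusted p = 0.138). Whether these transcripts lie in iNKT cells or in cells attached to them was not tested. Neutrophil (11 genes, resting median 0.13, camera adjusted p = 0.997), platelet (7 genes, 0.02, adjusted p = 0.917), CD8 T cell (6 genes, −0.06, adjusted p = 0.861), erythroid (9 genes, −0.08, adjusted p = 0.917) and γδ T cell (4 genes, 0.26, adjusted p = 0.917) markers were not called at rest. In the second response monocyte, neutrophil and erythroid medians were 0.20, 0.25 and 0.32 (camera adjusted p = 0.0088, 0.0088 and 0.0047, and 0.443, 0.363 and 0.316 with an estimated correlation). Those calls ended without Pre_stim replicate 2 (adjusted p = 0.254, 0.109 and 0.207) and with fry (0.336, 0.192 and 0.130). Monocyte and neutrophil calls also ended without Pre_unstim replicate 1 (0.172 and 0.149), and the neutrophil call with the filter (0.219).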
